A study of Mus musculus with 11 samples.

How the data were processed

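RNA of alveolar macrophages was measured on 11 Affymetrix arrays, 1 array for each sample. Per the labels, female C57BL/6J mice bought at 6 weeks of age received 5 injections over 10 days, either of PBS or of CpG 1826, an oligonucleotide that is a ligand of the DNA sensor Tlr9. The control group (n = 4) received PBS and was lavaged on day 10, the acute group (n = 3) received CpG and was lavaged on day 10, and the resolution group (n = 4) received CpG and was lavaged on day 30. Cells came from bronchoalveolar lavage and were purified by adherence. Per the labels, RNA was extracted with Trizol and labelled with biotin by a 3' IVT Pico kit.

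The submitters made the values with Affymetrix Expression Console, whose version and summary algorithm are not given in the sources used here. The deposited values are intensities on a linear scale, with the median of an array between 51.4 and 57.0. They were used without further scaling as log2(value + 1), and every log2 value below is on this scale. The table holds 28846 probe sets, each a transcript cluster, of which 31 are Affymetrix controls, 19572 have 1 gene symbol, 0 have several and 9243 have none. Gene identifiers of all 19572 named clusters were found in the RefSeq table of the mouse, and 0 symbols had to be updated. Of the 19505 distinct symbols 55 had several clusters, and the cluster with the highest mean over all 11 arrays stood for the gene. The genome build behind the array's annotation is not given in the sources used here, so no coordinates are printed.

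A cluster was kept where at least 3 of the 11 arrays lay above that array's own 40th percentile, which left 12144 genes. limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 11 arrays without a block, with 8 residual degrees of freedom and 4.48 prior degrees of freedom from empirical Bayes moderation. The 3 contrasts were acute versus control, resolution versus control and resolution versus acute, each two-sided, with Benjamini-Hochberg adjustment over the 12144 genes and a threshold of 0.05. Errors of differences are moderated standard errors (SE), and errors of group means are standard deviations (SD).

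Each array has 23 antigenomic probe sets, which match no mouse sequence. Their 90th percentile was taken as the array's background, a choice made after the data had been seen. A gene counted as below background in a group when none of that group's arrays lay above its own background. Where the mean of the lower of the compared groups did not exceed the mean background of its arrays by more than 1 SD, the fold was computed from the mean of the higher group to that background or, if higher, to the lower group's mean, and is given as "at least". No fold is given where both groups were below background. The number of arrays limits the precision of all values.

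Members of 33 gene lists were tested as groups, with 868 genes listed, 771 of them on the array and 632 among the genes tested. The lists cover interferon-gamma and type I interferon responses, MHC class II presentation, inflammatory cytokines and NF-kB targets, chemokines, alveolar macrophage identity, alternative activation, cell cycle, lipid handling, cholesterol biosynthesis, oxidative phosphorylation, glycolysis, iron and heme, inhibitory receptors, toll-like receptor signalling, complement, lysosome, antioxidant response, unfolded protein response, ribosomal proteins, and immediate early and handling stress genes. Marker lists of other cells cover monocytes, interstitial macrophages, neutrophils, T cells, NK and cytotoxic lymphocytes, B and plasma cells, dendritic cells, eosinophils, lung epithelium, endothelium, fibroblasts and red cells. The limma function camera compared each list with all other genes at a preset correlation of 0.01 between genes, with adjustment over 99 tests, and was repeated with the correlation estimated from the data. A list needed at least 3 measured members. The design, the lists and the alternatives were fixed before the data were examined, apart from those named as later choices. Lists of 14 clock genes and 9 glucocorticoid targets, and 25 gene families, were added after the values had been seen.

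Genes were named by a rule. It took the 10 largest rises and the 10 largest falls past the threshold whose arrays did not overlap between the compared groups, without symbols of unnamed gene models. It added up to 4 members of each list described, those with the largest change past the threshold or, where none passed, the member with the smallest p. It also took Cxcl9, Cxcl10, Ifng, Tlr9, Il10, Il6, Tnf, Il18, Il18bp, Il1b, Nos2, Arg1, Cd274, Siglecf, Marco, Pparg, Ly6c2, Ccr2, Itgam, Hmox1 and Cd163 in every comparison.

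The procedure was tested on simulated data with 12144 genes, of which 200 were changed. In acute versus control 28.4% of genes changed 1.5-fold were recovered, 82.1% of those changed 2-fold and 100% of those changed 4-fold. In resolution versus control these shares were 49.3%, 92.5% and 98.5%, and in resolution versus acute 17.9%, 88.1% and 100%. Of the unchanged genes 9, 6 and 4 were called in the 3 comparisons. A list shifted by 0.5 on the log2 scale was called in each of the 3 comparisons, with 0 other lists. Genes were simulated as independent of each other, so false list calls from correlation between genes could not show there. In the real data the estimated correlation was up to 0.519 for ribosomal protein genes and 0.906 for the red cell list.

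Alternatives were a shift of each array to a common median, quantile normalization, no filter and a stricter filter at the 60th percentile, the mean of a gene's clusters, each cluster on its own, an intensity trend, robust moderation, array quality weights, a fit of the compared groups alone, the replicate number as a block, a minimum of 2-fold, log2(value + 16), and leaving out each array in turn. The mean of the lung epithelium list as a covariate, leaving out control replicates 3 and 4 together, and counting only genes above background in a compared group were chosen after seeing the data. The differences over all genes in both comparisons with control were set against 100 simulated data sets of unchanged groups sharing the control arrays, and the genes changed in both against the 6 ways to give each comparison its own pair of controls. Of the 9243 clusters without a symbol, the 6601 that passed the same filter were tested apart from the named genes. Figures were drawn with matplotlib 3.10.9.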

Results

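Gene expression in alveolar macrophages, the resident phagocytes of the air spaces, was compared between mice injected with PBS (control, n = 4), mice at the end of a course of CpG injections that models macrophage activation syndrome (acute, n = 3) and mice lavaged on day 30 after the same course (resolution, n = 4). The arrays were alike in depth of signal, with a median intensity between 51.4 and 57.0, a background between 6.12 and 6.24 on the log2 scale and between 8730 and 8940 genes above background. Correlations across genes between arrays were 0.988 to 0.995 within groups and 0.975 to 0.993 between groups, where genes are not independent replicates. The first principal component held 43.9% of the variance and placed the 4 resolution arrays between 28.4 and 35.4, apart from the other 7 arrays at -27.3 to -12.4. Component 3 held 10.2% and set control replicate 4 apart at -34.9.

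**Figure D1:**
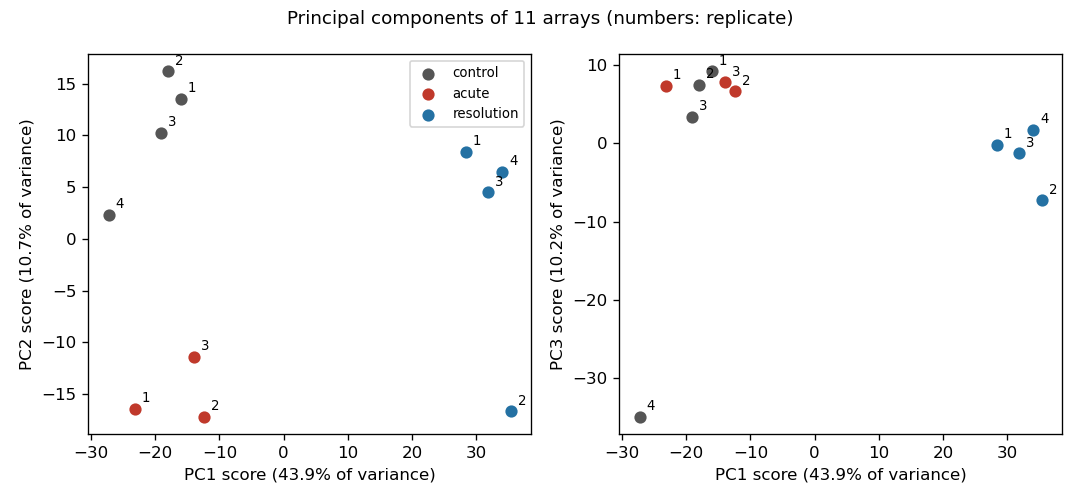
Principal components of log2 intensity over the 12144 genes tested, with the first component (43.9% of the variance) on the horizontal axes and the next components (10.7% and 10.2%) on the vertical axes. Each point is 1 array, and the 4 resolution arrays lie at positive values of the first component while the control and acute arrays lie at negative values.

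Acute versus control asks what the macrophages expressed at the end of the CpG injections. Genes induced by interferon-gamma were higher in the acute arrays. Cxcl9, a chemokine that attracts T cells, rose from a log2 level of 5.45 ± 0.44 (SD, n = 4), below background, to 8.14 ± 0.50 (SD, n = 3), at least 3.94-fold. Gbp2, a guanylate-binding protein, rose at least 3.16-fold, by 1.96 ± 0.23 (SE). Psmb9, a subunit of the immunoproteasome, rose 2.67-fold to 13.69 ± 0.38 (SD, n = 3), and Tap1, which carries peptides to MHC class I, rose 2.13-fold. H2-Q5, a nonclassical class I gene, rose 3.79-fold, and C1qa, a chain of the first complement component, rose 3.68-fold to 9.61 ± 0.49 (SD, n = 3). Of the 28 measured interferon-gamma induced genes 7 rose, 0 fell and 21 did not pass the gene test, while 18 rose adjusted over the list alone. The list as a whole was higher (adjusted p = 1.38e-22, and adjusted p = 0.00836 with an estimated correlation).

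Genes of the airway epithelium were higher in the same 3 acute arrays. The secretoglobins Scgb3a1 and Scgb1a1, secreted by club cells, rose 6.25-fold and 4.69-fold, Bpifa1, an airway surface protein, rose 5.85-fold to 12.36 ± 0.76 (SD, n = 3), and Cyp2f2, a cytochrome of club cells, rose 2.78-fold. Of 15 measured lung epithelium markers 4 rose and 0 fell (8 rose adjusted over the list alone), and all 15 had a positive difference (adjusted p = 5.2e-13, and adjusted p = 0.0165 with an estimated correlation). The mean level of this list was 8.84 ± 0.24 (SD, n = 3) in acute, 7.73 ± 0.16 (SD, n = 4) in control and 7.07 ± 0.16 (SD, n = 4) in resolution arrays. Tspan1, a tetraspanin, rose at least 6.01-fold, and Ctla2a, a protease inhibitor, rose 3.87-fold. With the mean of the epithelial list as a covariate, chosen after seeing the data, limma called 0 genes, with 728 at an unadjusted p under 0.05. Cxcl9 was then 2.87 ± 0.87 (SE) above control instead of 2.69 ± 0.28 (SE), with adjusted p = 0.749.

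Further marker lists of other cells also differed. Il2rb, a receptor chain for interleukins 2 and 15, rose at least 1.84-fold. The list of NK and cytotoxic lymphocytes was higher with 1 of 8 measured members past the gene threshold (3 rose and 1 fell adjusted over the list alone; adjusted p = 0.0021, and adjusted p = 0.265 with an estimated correlation). Cbr2, a carbonyl reductase listed with interstitial macrophages, rose 3.72-fold from 8.23 ± 0.21 (SD, n = 4) to 10.12 ± 0.34 (SD, n = 3). With C1qa it made up the 2 of 17 measured interstitial macrophage markers that rose (8 adjusted over the list alone; adjusted p = 5.53e-09, and adjusted p = 0.0498 with an estimated correlation). Of the 17, 8 also stand in another list. At resolution versus control Cbr2 differed by -1.47, as the airway genes Scgb1a1 (-1.44) and Cyp2f2 (-1.17) did, and unlike C1qa (1.51), so its rise need not come from interstitial macrophages. Complement genes had adjusted p = 0.0546 with 1 of 16 past the gene threshold, C1qa (4 adjusted over the list alone). They passed without control replicates 3 (0.0368) or 4 (0.00865), acute replicates 1 (0.0351) or 2 (0.0374) or resolution replicate 1 (0.0487), with the replicate block (0.0363) or without control replicates 3 and 4 together (0.00231). The T cell marker Cd3d was 0.80 ± 0.17 (SE) higher without passing the test (adjusted p = 0.102). Alas2, a heme synthesis enzyme of red cell precursors, differed by 4.36 ± 1.34 (SE) with a spread of 4.21 (SD, n = 3) among the acute arrays, and by 2.02 without acute replicate 1 and 6.10 without acute replicate 2. The red cell list of 3 genes was higher (0 rose and 0 fell, 1 rose adjusted over the list alone; adjusted p = 0.0272, and adjusted p = 0.461 with an estimated correlation), and had adjusted p = 0.661 without acute replicate 1 and 0.0504 without control replicate 3.

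Antigen presentation on MHC class II was higher as a list, with 0 of 13 measured genes past the gene threshold and 7 rising adjusted over the list alone (adjusted p = 1.73e-08, and adjusted p = 0.0498 with an estimated correlation). H2-Eb1, a class II beta chain, was 0.66 ± 0.13 (SE) higher (adjusted p = 0.0841). Lysosome and phagosome genes were lower as a list, with 0 of 28 past the gene threshold and 23 with a negative difference (adjusted p = 3.29e-05, and adjusted p = 0.0225 with an estimated correlation). Ctsa, a lysosomal carboxypeptidase, had a difference of -0.37 ± 0.11 (SE, adjusted p = 0.31). These lists, with the interferon-gamma, epithelial and interstitial macrophage lists, made up the 5 calls that held with an estimated correlation.

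A further 8 lists passed the threshold but not with an estimated correlation, and none of their members passed the gene test. Type I interferon genes were higher (0 of 30 past the gene threshold, 2 adjusted over the list alone, adjusted p = 7.36e-09, and adjusted p = 0.263 with an estimated correlation), with Ifi211 at 0.75 ± 0.17 (SE, adjusted p = 0.116). Ribosomal protein genes (0 of 42 past the gene threshold, 42 with a positive difference, adjusted p = 1.32e-05, and adjusted p = 0.594 with an estimated correlation) and inflammatory cytokines and NF-kB targets (0 of 28, 3 adjusted over the list alone, adjusted p = 0.00835, and adjusted p = 0.461 with an estimated correlation) were higher as lists, with Cd83, an activation marker, at 0.84 ± 0.17 (SE). Antioxidant genes were lower (0 of 20, also 0 adjusted over the list alone as for the lists that follow, adjusted p = 0.00288, and adjusted p = 0.461 with an estimated correlation). The NF-kB call ended without acute replicate 1 (adjusted p = 0.136). Oxidative phosphorylation genes were higher (0 of 49, adjusted p = 0.0195, and adjusted p = 0.777 with an estimated correlation), but not without control replicate 3 (0.151), acute replicate 2 (0.108) or acute replicate 3 (0.213). Iron and heme genes were lower (0 of 23, adjusted p = 0.0258, and adjusted p = 0.465 with an estimated correlation), with the iron exporter Slc40a1 at -1.02 ± 0.29 (SE), but not without control replicates 1 (0.0669) or 2 (0.0710) or acute replicates 2 (0.203) or 3 (0.147). Alveolar macrophage identity genes were lower (0 of 34, adjusted p = 0.0323, and adjusted p = 0.347 with an estimated correlation), but not without control replicates 1 (0.0586) or 2 (0.0668) or acute replicate 2 (0.196) or with the replicate block (0.0562). Cell cycle genes were lower (0 of 39, adjusted p = 0.0334, and adjusted p = 0.777 with an estimated correlation), but not without control replicates 1 (0.158) or 2 (0.665), acute replicate 1 (0.661) or resolution replicate 4 (0.0504).

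Few genes were lower in the acute arrays. Cd36, a scavenger receptor for oxidised lipids, fell 1.77-fold to 13.59 ± 0.15 (SD, n = 3). Me1, malic enzyme, fell at least 1.76-fold, Galnt6, a glycosyltransferase, fell 2.16-fold, Mamdc2 fell 2.13-fold, Sgcb, a sarcoglycan, fell 1.75-fold and Gsn, an actin-severing protein, fell 1.64-fold. Several cytokine and identity genes were measured at levels that did not pass the test. Il1b was 0.81 ± 0.20 (SE) higher (adjusted p = 0.187), Il18 stood at 16.40 ± 0.07 (SD, n = 3) against 16.32 ± 0.07 (SD, n = 4), and the differences of Il18bp, Il6, Tnf and Cd274 were 0.14, 0.24, -0.20 and 0.15. Siglecf, Marco, Pparg and Itgam, genes of resident and recruited macrophages, differed by -0.00, -0.30, -0.09 and -0.20, and the heme oxygenase Hmox1 by -0.73 ± 0.27 (SE). Arg1 differed by -1.98 ± 1.16 (SE) with a spread of 3.06 (SD, n = 4) among controls, and by -0.50 without control replicate 4, where it stood at 11.52. Cxcl10, Ifng, Il10, Ccr2 and Cd163 were below background in both groups, and Tlr9, Nos2 and Ly6c2 were too dim to be tested.

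**Figure D2:**
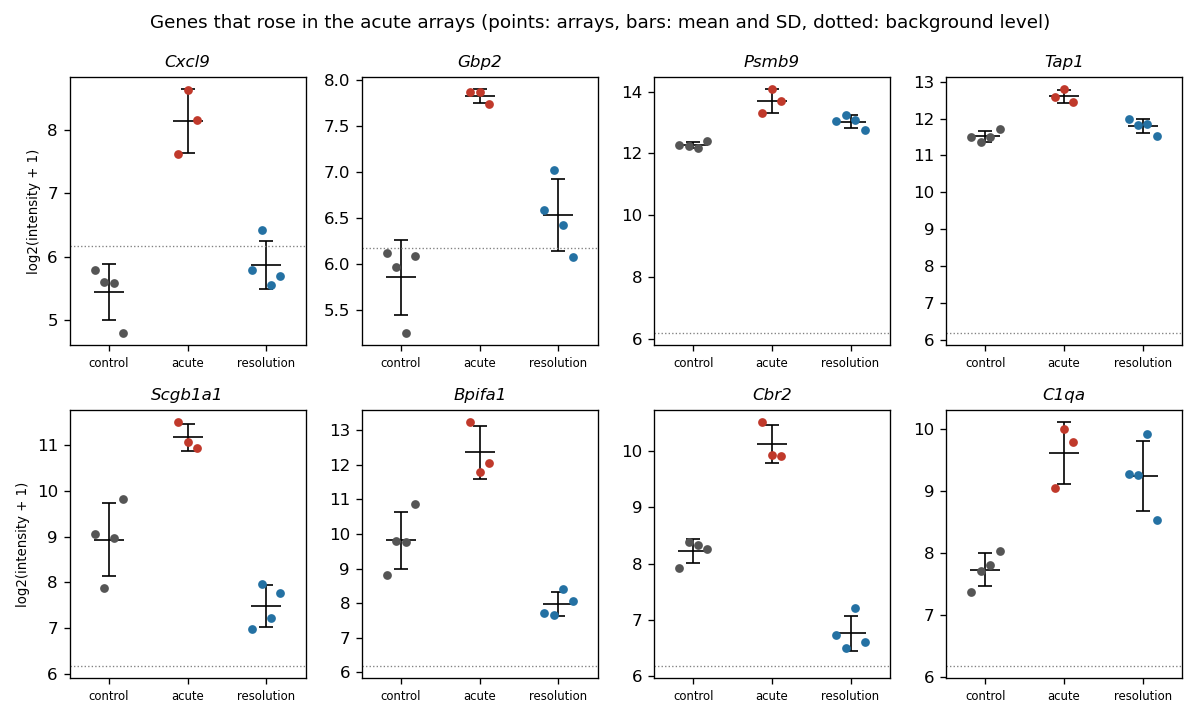
Log2 intensity of 8 genes in the control, acute and resolution arrays, with points for arrays, bars for the mean and SD of each group, and a dotted line at the mean background of 6.18. Cxcl9, Gbp2, Psmb9, Tap1, C1qa and the airway genes Scgb1a1 and Bpifa1 and Cbr2 are higher in the 3 acute arrays than in the 4 controls.

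In all, 29 of the 12144 genes tested changed, 23 higher and 6 lower, and 24 of them by at least 2-fold. At an unadjusted p under 0.05 there were 1099 genes, and the arrays of the compared groups did not overlap for 10.1% of genes, where chance gives 5.71%. After scaling to a common median the split was 25 higher and 3 lower, and after quantile normalization 29 and 3. Without acute replicate 2 limma called 6 genes and without acute replicate 3 it called 10 (9 of them among the 29). Without control replicate 1 it called 13 and without control replicate 2 it called 18 (16 among the 29). Cxcl9, Gbp2, Psmb9 and Cbr2 stayed past the threshold without each array in turn. Without acute replicate 2 the calls of Tspan1, Ctla2a and Tap1 (adjusted p = 0.0620 for each) and of the other 13 genes named as changed ended, with adjusted p of up to 0.227. Without acute replicate 3 the calls of Scgb3a1, Bpifa1, Scgb1a1, Il2rb, H2-Q5, Me1, Galnt6, Mamdc2, Cd36, Sgcb, Gsn, C1qa and Cyp2f2 ended (adjusted p = 0.0823 to 0.143), and the same 13 ended without control replicate 1 (adjusted p = 0.0633 to 0.111). Control replicate 2 decided the calls of Scgb3a1, Bpifa1, Me1, Galnt6, Mamdc2, Cd36, Sgcb, Gsn, C1qa and Cyp2f2 (adjusted p = 0.0544 to 0.0950 without it). Acute replicate 1 decided those of Scgb3a1, Bpifa1, Scgb1a1, Me1, Sgcb, Gsn and Cyp2f2 (0.0531 to 0.134 without it). Control replicate 3 decided those of Bpifa1, Scgb1a1, H2-Q5, Galnt6, Sgcb and Cyp2f2 (0.0505 to 0.0757), and control replicate 4 those of H2-Q5, Me1, Sgcb and Gsn (0.0616 to 0.0777). Leaving out single resolution arrays, which share in the estimate of the spread, gave adjusted p of 0.0507 to 0.0639 for Scgb3a1, Bpifa1, Me1, Sgcb, Gsn and Cyp2f2.

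Resolution versus control asks what differed on day 30 in mice that had received CpG, and the groups also differ in the day of lavage. Genes of the antioxidant response fell as a list (adjusted p = 2.24e-08), but not with an estimated correlation (adjusted p = 0.246). Of 20 measured 11 fell and 0 rose (12 and 1 adjusted over the list alone). Slc7a11, the cystine importer, fell 19.7-fold to 11.05 ± 1.28 (SD, n = 4), Hmox1 fell 15.3-fold from 15.57 ± 0.30 to 11.63 ± 0.54 (SD, n = 4), Srxn1, which repairs peroxiredoxins, fell 10.6-fold, and Gclc, which makes the precursor of glutathione, fell 5.64-fold. Plpp3, a lipid phosphatase, fell 85.9-fold, the largest fall as measured. The kinase gene Plk2 fell at least 66.1-fold to 6.19 ± 0.42 (SD, n = 4), a bound that leaves its rank against Plpp3 open. Met, the receptor of hepatocyte growth factor, fell at least 6.48-fold, Cxcr1, a chemokine receptor, 11.2-fold, Ptgir, the prostacyclin receptor, 10.1-fold, Il1f9, a cytokine of the interleukin-1 family, at least 7.32-fold, and the repressor gene Bcl6 6.97-fold. The control mean of Cxcr1 was raised by control replicate 4, at 14.72 against 13.02 in the other controls.

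Inflammatory cytokines and NF-kB targets fell in the resolution arrays, with 9 of 28 measured members lower and 1 higher (12 and 2 adjusted over the list alone; adjusted p = 8.71e-06, and adjusted p = 0.263 with an estimated correlation). The NF-kB inhibitors Tnfaip3 and Nfkbie fell 5.32-fold and at least 4.05-fold, Icam1, an adhesion molecule, 3.85-fold and Nfkb2, an NF-kB subunit, 3.51-fold. Cholesterol biosynthesis fell with 10 of 20 measured genes lower and 0 higher (14 and 0 adjusted over the list alone; adjusted p = 2.51e-06, and adjusted p = 0.315 with an estimated correlation), among them Fdft1, squalene synthase, by 1.17 ± 0.13 (SE), and the sterol enzyme genes Msmo1, Hsd17b7 and Sc5d, which fell by 1.07, 0.95 and 0.89. The call of Sc5d (adjusted p = 0.0274) ended without control replicates 2 (0.0742) or 4 (0.0710) or resolution replicates 3 (0.0794) or 4 (0.0714). Iron and heme genes fell in 9 of 23 cases and rose in 2 (9 and 3 adjusted over the list alone; adjusted p = 0.00641, and adjusted p = 0.429 with an estimated correlation). The iron transporters Slc40a1, Slc11a1 and Slc11a2 fell at least 6.74-fold, 5.61-fold and 2.66-fold. Lysosome genes fell in 6 of 28 cases and rose in 2 (9 and 2 adjusted over the list alone; adjusted p = 0.0187, and adjusted p = 0.136 with an estimated correlation), with Atp6v1a, a subunit of the proton pump, 3.09-fold lower, the galactosidase Gla 3.06-fold lower and Ncf1, an oxidase subunit, 1.88-fold higher. Lung epithelium markers were lower than in control, with 4 of 15 lower and 0 higher (5 and 0 adjusted over the list alone; adjusted p = 0.00641, and adjusted p = 0.264 with an estimated correlation), namely Scgb3a2, Bpifa1, Scgb1a1 and Cyp2f2 at 3.69-fold, 3.59-fold, 2.71-fold and at least 2.25-fold.

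Immediate early genes, which respond to stimuli within minutes and also to handling of cells, rose as a list (adjusted p = 0.02, and adjusted p = 0.433 with an estimated correlation). Of 21 measured members 9 rose and 3 fell (10 and 3 adjusted over the list alone). Fosb rose 19.4-fold from 9.14 ± 0.42 to 13.42 ± 0.68 (SD, n = 4), Nr4a1, an orphan nuclear receptor, 4.26-fold, Btg2 2.84-fold and Egr1 2.76-fold. With control replicates 3 and 4 both left out, chosen after seeing the data, this list had adjusted p = 0.0761. Ccl2, the chemokine for monocytes, rose at least 7.75-fold to 9.32 ± 0.45 (SD, n = 4). Further rises were those of Themis2 (9.77-fold), a signalling protein of myeloid and B cells, Tifab (8.56-fold), Il6ra (7.74-fold), the interleukin-6 receptor, Ffar2 (at least 7.63-fold), a receptor for short-chain fatty acids, Rcan1 (6.67-fold), a calcineurin inhibitor, Id1 (6.56-fold), the clock gene Per2 (at least 5.61-fold) and Trim47 (at least 4.50-fold).

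Members of several lists moved in both directions, and those lists did not pass. Of 28 interferon-gamma induced genes 7 rose and 4 fell (8 and 4 adjusted over the list alone; adjusted p = 0.199), with Gbp7, Fcgr1 and Gbp8 3.19-fold, 3.14-fold and 2.33-fold higher and Acod1, the itaconate enzyme, at least 3.08-fold lower. Cxcl9 was 0.42 ± 0.26 (SE) above control (adjusted p = 0.307), while C1qa rose 2.85-fold. Of 34 alveolar macrophage identity genes 6 rose and 8 fell (6 and 8 adjusted over the list alone; adjusted p = 0.828), with Krt19 and Cidec 3.43-fold and 2.52-fold higher and Bhlhe41 and the lipid binding protein Fabp4 2.69-fold and 2.29-fold lower. Of 30 lipid handling genes 8 rose and 6 fell (9 and 6 adjusted over the list alone; adjusted p = 0.743), with Angptl4 and the cholesterol exporter Abcg1 4.17-fold and 2.68-fold higher and Nr1h3, a sterol receptor, 2.16-fold lower. Of 27 toll-like receptor genes 4 rose and 7 fell (8 and 9 adjusted over the list alone; adjusted p = 0.743), with Tlr5, Tlr3 and Irf8 3.97-fold, 3.26-fold and 2.21-fold higher and Cd14 2.01-fold lower. The costimulatory genes Cd80 and Cd86, listed with MHC class II, rose 2.93-fold and fell 1.71-fold (list adjusted p = 0.389). Pparg rose by 0.75 ± 0.12 (SE), Il1b by 0.75 ± 0.19 (SE), and Cd274, a ligand of an inhibitory receptor, fell 2.00-fold. Ccr2 rose at least 1.15-fold, a call that ended without control replicates 3 (adjusted p = 0.0662) or 4 (0.0602) or resolution replicates 2 (0.0659) or 4 (0.0598). Cbr2 fell 2.76-fold, and Cd3d, below background in both groups, differed by -0.72 (adjusted p = 0.00722). The T cell list had adjusted p = 0.0518 with 1 of 10 members past the gene threshold. It passed without control replicates 1 (0.0488) or 2 (0.0184), acute replicates 2 (0.0374) or 3 (0.0439) or resolution replicates 1 (0.0438) or 3 (0.0372) or with the replicate block (0.0470). Il18, Il18bp, Il6, Tnf, Arg1, Siglecf, Marco and Itgam differed by 0.28, -0.37, -0.59, -0.10, -2.04, 0.23, -0.35 and -0.52 without passing, although Il6 passed without resolution replicate 4 (adjusted p = 0.00486) and Arg1 differed by -0.56 without control replicate 4. Cxcl10, Ifng, Il10 and Cd163 were below background in both groups.

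**Figure D3:**
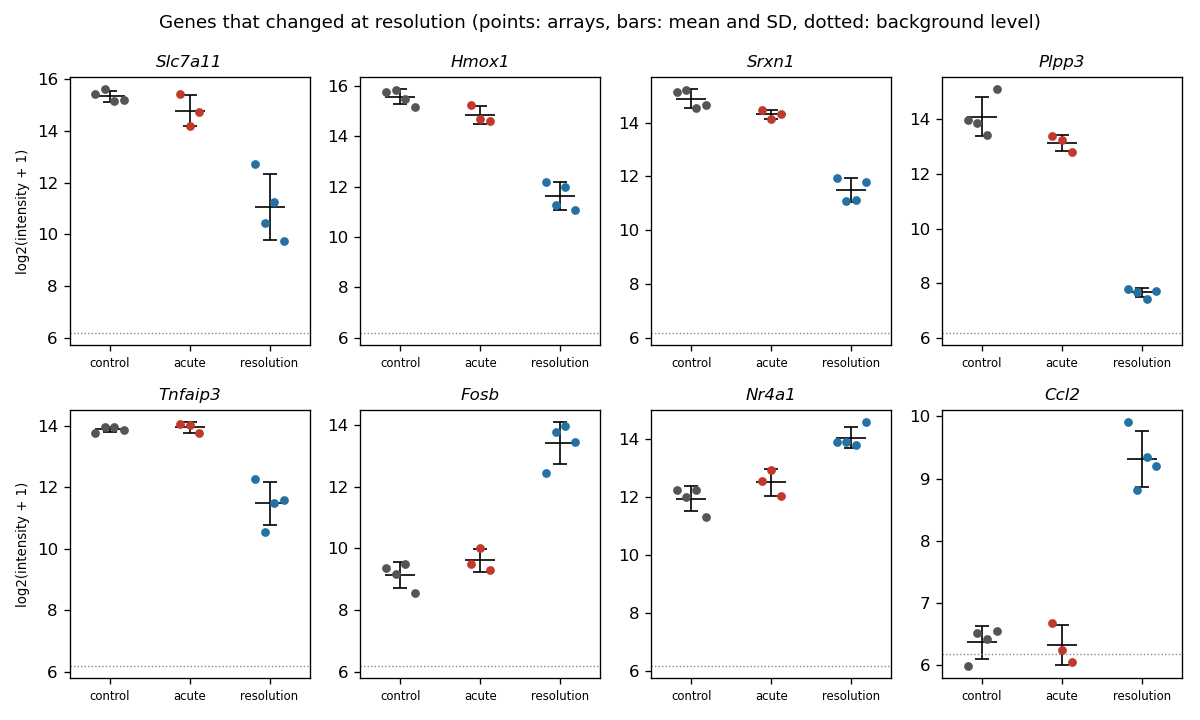
Log2 intensity of 8 genes in the control, acute and resolution arrays, with points for arrays, bars for the mean and SD of each group, and a dotted line at the mean background of 6.18. Slc7a11, Hmox1, Srxn1, Plpp3 and Tnfaip3 are lower and Fosb, Nr4a1 and Ccl2 higher in the 4 resolution arrays than in the other 7.

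In total 2259 genes changed at resolution against control, 1166 higher and 1093 lower, of which 550 changed by at least 2-fold. After scaling to a common median 893 were higher and 1198 lower, and after quantile normalization 1001 and 1259, so which direction held more genes depends on the scaling. The arrays did not overlap for 22.7% of genes, where chance gives 2.86%, and 78 of the changed genes were below background in both groups. Without control replicate 3, 907 were higher and 959 lower. Without control replicates 3 and 4, 1494 genes changed (690 higher and 804 lower), and with the epithelial covariate 357, both settings chosen after seeing the data. Since the day 30 arrays are all from 1 group, the day of lavage and the recovery from CpG cannot be told apart.

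Resolution versus acute asks what changed between the end of the injections and day 30 in mice that received CpG. The airway genes that were high in the acute arrays fell. Bpifa1 fell 21.0-fold from 12.36 ± 0.76 (SD, n = 3) to 7.97 ± 0.34 (SD, n = 4), Scgb3a2 20.4-fold, Scgb3a1 13.6-fold and Scgb1a1 12.7-fold, Bpifb1, another airway surface protein, at least 13.2-fold and Cyp2a5, a cytochrome, at least 11.1-fold. Of 15 lung epithelium markers 9 fell and 0 rose (12 and 0 adjusted over the list alone; adjusted p = 1.14e-09, and adjusted p = 0.0225 with an estimated correlation), the single list call here that held with an estimated correlation. Tspan1 fell at least 5.89-fold and Cbr2 10.3-fold.

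Interferon-gamma induced genes fell, with 11 of 28 lower and 2 higher (16 and 2 adjusted over the list alone; adjusted p = 4.98e-06, and adjusted p = 0.104 with an estimated correlation). Cxcl9 fell at least 3.86-fold to 5.87 ± 0.38 (SD, n = 4), Gbp2 at least 2.45-fold, Irgm1, a GTPase of cell defence, at least 2.23-fold and Acod1 at least 5.19-fold. Ifi211 fell 2.49-fold, among 3 of 30 type I interferon genes that fell and 1 that rose. Their list had adjusted p = 0.056 (0.730 with an estimated correlation). It passed without acute replicates 1 (0.0124) or 3 (0.0227), control replicate 4 (0.0347), resolution replicate 1 (0.0362) or control replicates 3 and 4 together (0.0393), with no filter (0.00838) or with the replicate block (0.0399). MHC class II genes fell in 5 of 13 cases and rose in 1 (6 and 1 adjusted over the list alone; adjusted p = 0.0414, and adjusted p = 0.441 with an estimated correlation), with H2-Eb1, H2-Oa and Cd86 falling by 0.63, 0.75 and 0.71 and Cd80 2.30-fold higher. The list call ended without acute replicate 2 (0.102), resolution replicate 1 (0.0659) or resolution replicate 3 (0.0504) and after scaling to a common median (0.0523). The NK and cytotoxic list fell with 3 of 8 lower (4 lower and 1 higher adjusted over the list alone; adjusted p = 0.0161, and adjusted p = 0.379 with an estimated correlation), namely Il2rb at least 1.80-fold, Klrd1, a killer cell receptor, at least 2.49-fold and Klrk1, near background, by 0.70. T cell markers fell with 2 of 10 lower, Cd3d at least 1.28-fold and Lat by 0.90 (adjusted p = 0.0238, and adjusted p = 0.461 with an estimated correlation), but not without acute replicate 2 (0.117) or resolution replicate 2 (0.0624). Interstitial macrophage markers fell in 4 of 17 cases, among them Cbr2 and Tmem176a, which fell by 0.83 (6 adjusted over the list alone; adjusted p = 0.0184, and adjusted p = 0.418 with an estimated correlation), but not without acute replicate 2 (0.0660) or resolution replicate 4 (0.0672).

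The antioxidant, NF-kB, cholesterol and iron lists fell here too, though none of them passed with an estimated correlation. Among antioxidant genes 10 of 20 fell (10 adjusted over the list alone; adjusted p = 2.47e-06, and adjusted p = 0.279 with an estimated correlation), with Slc7a11, Hmox1, Srxn1 and Gclc 13.4-fold, 9.27-fold, 7.05-fold and 3.77-fold lower. Of the NF-kB list 15 of 28 fell (16 adjusted over the list alone; adjusted p = 5.53e-09, and adjusted p = 0.123 with an estimated correlation), with Tnfaip3, Icam1, Bcl3 and Nfkbie 5.55-fold, 4.37-fold, 4.30-fold and at least 3.92-fold lower. Of cholesterol genes 7 of 20 fell (9 adjusted over the list alone; adjusted p = 1.32e-05, and adjusted p = 0.347 with an estimated correlation), including Fdps, Fdft1, Stard4 and Idi1, which fell by 1.21, 0.99, 0.96 and 0.90. Iron and heme genes fell in 7 of 23 cases and rose in 1 (9 and 3 adjusted over the list alone; adjusted p = 0.0471, and adjusted p = 0.541 with an estimated correlation), with Slc40a1, Slc11a2 and Slc11a1 at least 3.32-fold, 2.56-fold and 2.46-fold lower. This call ended without control replicates 1 (0.0525) or 3 (0.0559), acute replicate 1 (0.184) or resolution replicates 2 (0.0953), 3 (0.0515) or 4 (0.0504), with log2(value + 16) (0.0522) or with the replicate block (0.0568). Plpp3 fell 44.6-fold and Plk2 at least 38.8-fold, and Atp6v1a and Gla of the lysosome list 2.16-fold and 2.07-fold, while Ncf1 rose 1.76-fold.

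Genes higher at resolution than in the acute arrays were led by Fosb (14.0-fold), Sgms1, a sphingomyelin synthase (9.50-fold), and Ccl2 (at least 7.97-fold). They included Tifab (7.35-fold), Ffar2 (6.36-fold), Themis2 (5.84-fold), Trerf1 (5.43-fold), the peroxisomal transporter Abcd2 (5.40-fold), Trim47 (at least 4.43-fold) and Gapt (at least 3.17-fold). Immediate early genes rose in 8 of 21 cases and fell in 3 (9 and 3 adjusted over the list alone; adjusted p = 0.0471, and adjusted p = 0.461 with an estimated correlation), with Nr4a1, Btg2 and Egr1 2.90-fold, 2.82-fold and 2.63-fold higher, but not without control replicates 2 (0.0579) or 3 (0.0559), acute replicates 1 (0.0667) or 3 (0.115) or resolution replicates 3 (0.0577) or 4 (0.0714), with log2(value + 16) (0.0522) or with the replicate block (0.0616). Krt19 and Cidec rose 4.02-fold and 2.31-fold and Bhlhe41 and Fabp4 fell 2.24-fold and 2.12-fold, while Tlr5 and Tlr3 rose 4.74-fold and 2.92-fold and Cd14 fell 2.76-fold. Abcg1 and Angptl4 rose 2.84-fold and 2.65-fold and Nr1h3 fell 2.11-fold, Pparg rose by 0.84 ± 0.13 (SE), and Cd274 fell 2.22-fold. Il6 fell by 0.83 ± 0.23 (SE). Il18, Il18bp, Il1b, Tnf, Siglecf, Marco, Itgam and Ccr2 differed by 0.20, -0.51, -0.06, 0.10, 0.23, -0.05, -0.32 and 0.56 without passing, though Ccr2 passed without resolution replicate 3 (adjusted p = 0.0315), and Alas2 differed by -4.20 ± 1.34 (SE, adjusted p = 0.0546), by -1.86 without acute replicate 1 (0.0773) and by -5.94 without acute replicate 2 (0.00722). Arg1, Cxcl10, Ifng, Il10 and Cd163 were below background in both groups.

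Between the acute and resolution arrays 1755 genes changed, 943 higher and 812 lower, of which 488 changed by at least 2-fold. After scaling to a common median 676 were higher and 987 lower, and after quantile normalization 685 and 1151. The arrays did not overlap for 26.3% of genes, where chance gives 5.71%. Without acute replicate 1 there were 1069 genes, and with the epithelial covariate limma called 0, with 973 at an unadjusted p under 0.05. Calls of named genes that ended without acute replicate 1 were those of H2-Oa (adjusted p = 0.0513), Cd86 (0.0684), Fdps (0.0958), Idi1 (0.116), Slc11a1 (0.160), Gla (0.167), Lat (0.108), Klrk1 (0.152) and Il6 (0.130). Without acute replicate 2 those of H2-Oa, Cd86, Fdps, Slc11a1, Tmem176a, Lat, Klrk1 and Il6 ended (0.0516 to 0.104), and without acute replicate 3 those of H2-Oa, Fdps, Gla, Lat, Klrk1 and Il6 (0.0698 to 0.134). Each of the 4 resolution arrays likewise decided some of the calls of H2-Oa, Fdps, Idi1, Slc11a1, Gla, Lat, Klrk1 and Il6 (adjusted p = 0.0532 to 0.0984 without it), and control replicates 1, 2 and 3 those of Slc11a1, Klrk1 and Gla (0.0501 to 0.0549).

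**Figure D4:**
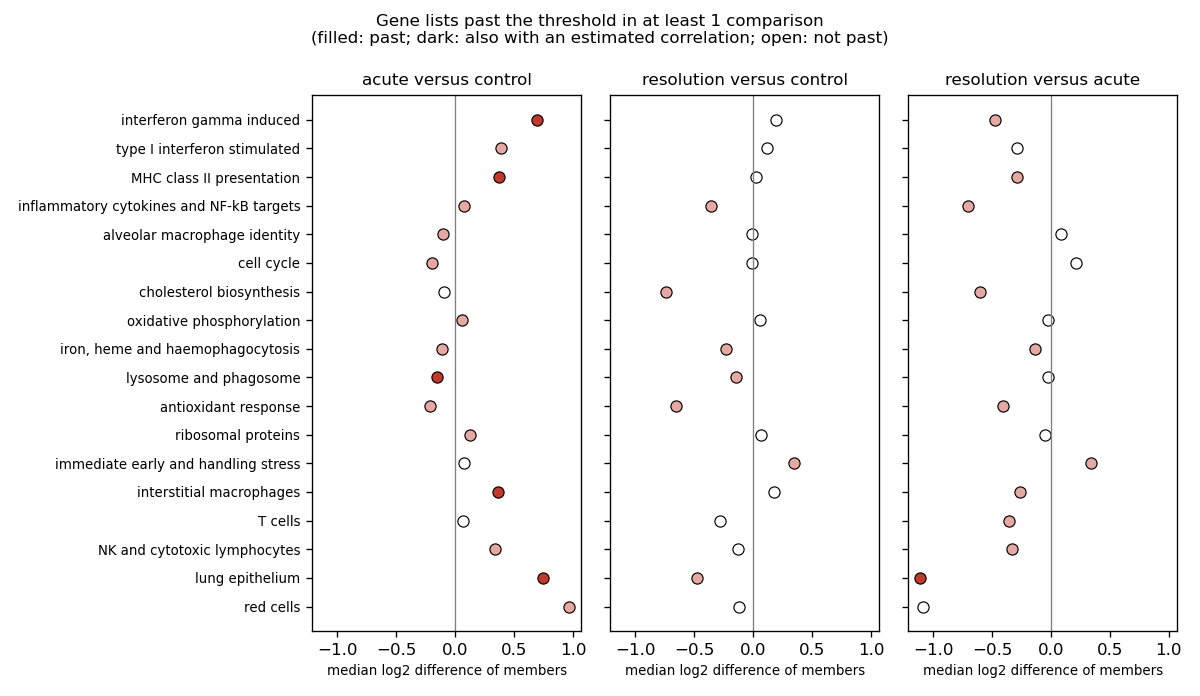
Median log2 difference of the measured members of 18 gene lists in the 3 comparisons, on the horizontal axis. Filled points passed the threshold at the preset correlation, dark points also with an estimated correlation, and open points did not pass, so the interferon-gamma and lung epithelium lists are dark and positive for acute versus control.

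The day 30 arrays also address how much of the acute difference was left. Of the 29 genes changed in acute versus control 13 also changed at resolution versus control, 8 in the same and 5 in the opposite direction, and 16 did not pass there. Those higher in both were Gbp2, C1qa, Psmb9, Gbp7 and Mndal, an interferon-inducible gene, and those lower in both were Cd36, Galnt6 and Me1, where Mndal is named after its values were seen. Chance gives 2.21 genes higher in both and 0.540 lower in both. Tspan1, Bpifa1, Scgb1a1, Cbr2 and Cyp2f2 were higher in acute and lower at resolution than in control, where chance gives 2.07. Resolution versus acute uses the acute arrays by which the 29 genes were selected, which favours a move back, and no value for unchanged groups was computed. There 25 of the 29 changed, with 20 of the higher genes lower again and Mamdc2, Sgcb and Gsn higher again. The comparisons share the control arrays, and simulated unchanged groups sharing them gave a covariance of the differences over all genes of 0.0161, against 0.0425 observed, but a higher correlation (r = 0.463 against 0.322 observed) and a higher share of genes with the same sign (65.4% against 61.3%). The simulation gave all arrays the same SD per gene. Control replicate 4 widened the control spread of some genes, such as Awat1 (SD 3.99 in control, 0.05 in acute and 0.12 in resolution arrays). The simulated covariance may therefore be too low, and the gap to the observed one does not show a shared response. With the 6 ways of giving each comparison its own pair of controls the number in the same direction was 8, 2, 5, 2, 4 and 2, beside 6, 3, 1, 5, 3 and 1 in the opposite direction, and the covariance was 0.00684 to 0.0294. Without control replicate 1, control replicate 2 or acute replicate 3 the number was 3, without acute replicate 2 it was 2, and without resolution replicate 3 it was 5.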

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

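The tests of a lower macrophage share, handling stress, a separate processing run, clock phase, other cells in control replicate 4 and carry-over, and the covariate itself, were chosen only after the results they address had been seen. Those of the splits, the bounds for the epithelial source and the swapped label were set before.

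Other splits of the compared arrays were counted for each comparison. In each comparison 1 of the 35 splits, the real one, gave as many changed genes. This is the smallest share that 35 splits can give, so chance is argued against as the source of these counts but not excluded. Other splits also take differences between the real groups into the spread, which lowers their counts. Acute versus control gave 29 genes against at most 4 in another split, resolution versus control 2259 against 0 in every other split, and resolution versus acute 1755 against at most 162. At an unadjusted p under 0.05 limma gave up to 1104, 1238 and 2404 genes in other splits, where the real counts were 1099, 3804 and 3497, so the unadjusted count of acute versus control was reached by another split.

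Interferon-gamma induced genes and airway epithelial genes were higher in the same 3 acute arrays, and epithelial RNA in the lavage is a candidate source of the interferon-gamma part. To weigh a lower share of macrophages as the source of the epithelial part, the epithelial list was set against other cells. The median of the 15 epithelial markers lay 0.68 (95% bootstrap interval 0.24 to 1.48) above the pooled median of the other 11 lists of other cells, which was 0.07, and 1.88 (0.70 to 2.57) above it among genes above background in all controls. These intervals met the bound set against a lower share, but they resample markers and give no spread between animals. Set against single lists the interval included 0 for interstitial macrophages, NK and cytotoxic lymphocytes and red cells. Dim pooled markers could hardly show a rise, with 0 of 8 NK and cytotoxic markers above background in all controls. Strong ones, such as Clec4e at 16.32 in control replicate 4, may come from the macrophages themselves. The comparison therefore does not decide the question. With the epithelial mean as a covariate the median difference of the interferon-gamma list was 0.65 (0.51 to 0.87 with 1 array left out) instead of 0.69, which met the bound of 0.35 set against the epithelial source but not by more than its spread, since 95% intervals reached below that bound, from -0.11 to 1.41 by a jackknife over the same fits and from 0.31 to 1.16 by a bootstrap of residuals, and for the list mean of 0.73 ± 0.24 (SE, 0.73 ± 0.08 without the covariate) from 0.17 to 1.29. The bootstrap interval alone lay above the 0.23 set in favour of the source, and these intervals were added after the median was seen and turned the reading from excluded to open. The covariate raised the unscaled standard error of each difference from 0.764 to 2.24 and the 29 calls ended, because of the larger error for Gbp2 at 1.96 ± 0.23 (SE) before and 2.01 ± 0.71 after and for Psmb9 at 1.42 ± 0.17 before and 1.82 ± 0.50 after, so epithelial RNA and a response of the macrophages to CpG, the untested biological explanation, cannot be told apart here. Of the 15 markers 0 stand in another list and 8 were above background in all controls, the most abundant were Scgb3a2, Bpifa1 and Sftpc at 13.27, 12.36 and 11.58 in acute against 10.81, 9.81 and 10.93 in control arrays, and the labels state purification by adherence.

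Of 20 antioxidant genes 11 fell and of 21 immediate early genes 9 rose in resolution versus control, list calls that ended with an estimated correlation (adjusted p = 0.246 and 0.433). For a shift in clock phase as the source of the Per1 and Per2 part, 90% of the other clock genes above background, 9 of 10, had 95% intervals within the size of the Per1 difference of 1.12, with Bhlhe41 the exception. This met the bound set against a shift. Among the 9, however, Cry2, Dbp and Nr1d1 had group means at or below the mean background of 6.18, where a change could hardly show. Arntl and Clock, well above background, differed by -0.18 and -0.26 without passing limma's test. Cry1 fell by 0.52 (limma adjusted p = 0.0117) and Bhlhe41 differed by -1.43, so a shift in clock phase stays open. Handling stress or a delay before lysis may account for the immediate early part, but 42.9% of the list rose, 9 of 21, and 3 fell (Jun, Atf3 and Klf6, named after their values were seen), between the bounds set for and against it, which leaves it open. A separate processing run of the day 30 arrays cannot be told apart from the group, since all day 30 arrays are in it, and the poly-A spike-ins stood at 6.08 ± 0.24 (SD, n = 4) against 6.26 ± 0.16 (SD, n = 7) in the other arrays (exact permutation p = 0.164, two-sided over 330 splits). Both spike-in means lay near the mean background of 6.18, so the spike-ins could hardly show a difference between runs. Recovery from CpG and the later day of lavage stay open as untested biological explanations.

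Control replicate 4 stood apart from the other controls, with 184 genes more than 1 log2 unit higher and 77 lower, and no biological explanation was tested. A swap with an injected array is argued against, since its highest position on an axis from the other controls (0) to an injected group (1) was 0.333, and -0.000517 on the resolution axis. The 0.333 was on the acute axis, where control replicates 1, 2 and 3, each left out in turn, lay at 0.119, -0.143 and 0.104. Control replicate 4 thus lay furthest of the controls towards the acute group. Cells of another type could add RNA, and among 12 marker lists the eosinophil list had the highest median excess, 1.19, with Ear6 at 13.71 against 12.29, Alox15 at 7.05 against 4.88, Ccr3 at 6.29 against 5.10, Prg3 at 5.66 against 5.19 and Cd24a at 9.05 against 9.09 in the other controls, which stays open because the excess alone met the bound while a requirement that all members above background exceed 1, added after the excess had been seen, was not met. These 5 genes stand in 0 other lists, 2 of them were above background in all controls, the untested genes Prg2, Epx and Il5ra stood at 6.95, 3.91 and 4.58 against 4.42, 4.30 and 3.80, and adherence would remove most cells that do not attach. Of 15 lung epithelium markers 9 were above background in control replicate 4. Of those, 4 exceeded the other controls by more than 1. Scgb3a2 stood highest at 11.92 with an excess of 1.49, while the median excess of the epithelial list was -0.04. Carry-over of RNA from control replicate 4 into control replicate 3 also stays open, since over 20 genes the share of the control replicate 4 excess seen there had a median of 2.12% and quartiles of 1.41% and 3.70%, a ratio of 2.62 between the bounds set, while the injected arrays had medians of -0.416% to 1.63%.

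Single arrays lay far from the rest of their group in 18 of 334 groups of 4 arrays tested over the named genes and lists, where chance gives about 1 in 20. In control replicate 4, Cd83 stood at 7.60 against a mean of 8.22 in the other controls, Siglecf at 14.51 against 15.06, Cxcr1 at 14.72 against 13.02, Mmp12 at 16.95 against 15.43 and Igf1 at 14.59 against 13.03. Control replicate 2 had Msmo1 at 9.98 against 9.58. In resolution replicate 4, Il6ra stood at 14.33 against 13.74, Nr4a1 at 14.57 against 13.86 and Ncf1 at 11.39 against 10.94. Resolution replicate 2 had Egr1 at 10.15 against 10.96, Abcg1 at 13.96 against 14.28, Batf3 at 8.75 against 7.68, Calcrl at 9.73 against 10.33, the alveolar macrophage identity mean at 13.58 against 13.64 and the ribosomal protein mean at 15.57 against 15.35. In resolution replicate 1, Acod1 stood at 6.59 against 4.61 and the monocyte mean at 9.89 against 9.65, and in resolution replicate 3 Tmem176a stood at 7.02 against 6.37.

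Transcript clusters without a gene symbol, which no comparison above uses, also differed between groups. Of 6601 tested, 5 changed in acute versus control (4 higher and 1 lower), 168 in resolution versus control (95 and 73) and 142 in resolution versus acute (103 and 39).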

How the results depend on the processing

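The epithelial covariate, leaving out control replicates 3 and 4 together, and counting only genes above background were chosen after seeing the data, and all other alternatives before. The number of arrays and, for genes near background, the signal limit what can be resolved: counting only genes above background left 29, 2181 and 1669 genes in acute versus control, resolution versus control and resolution versus acute.

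Of the 29 genes of acute versus control 25 were kept after a shift to a common median and 26 after quantile normalization. The count was 51 with an intensity trend, 54 with array quality weights and 16 in a fit of the compared groups alone, which leaves fewer degrees of freedom. It was 0 with the epithelial covariate, where limma gave 728 genes at an unadjusted p under 0.05 and standard errors were larger, and 6 to 29 when each array was left out in turn. For resolution versus control the count was 550 at a minimum of 2-fold, by construction, 357 with the covariate and 1494 without control replicates 3 and 4. For resolution versus acute it was 488 at a minimum of 2-fold, 0 with the covariate (973 at an unadjusted p under 0.05), and 1069 to 1837 leaving out each array. With the replicate number as a block the counts were 25, 2120 and 1455, and across genes the residuals of arrays sharing a number in different groups had r between -0.123 and 0.0873 in 10 pairs. These values gave no sign that the numbers pair the samples, but they cannot exclude it, and the labels do not state it. Across the median shift and quantile normalization the median of all genes moved by less than 0.1, and the median of 0 of the 15, 7 and 11 lists past the threshold changed sign.

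With an estimated correlation 5, 0 and 1 lists passed in the 3 comparisons, where camera with the preset correlation called 15, 7 and 11. Apart from leaving out single arrays, further list calls gained in acute versus control were chemokines with the replicate block (adjusted p = 0.0432) and without control replicates 3 and 4 (0.0183) and T cells without a filter (0.00634) and without control replicates 3 and 4 (0.0453), and in resolution versus acute the cell cycle without a filter (0.0347) and with the block (0.0470). With single arrays left out 12 to 17 lists passed in acute versus control and 8 to 12 in resolution versus acute, and not all calls gained there are named. Without control replicates 3 and 4 the NF-kB (0.0742), oxidative phosphorylation (0.0657) and red cell (0.0761) calls of acute versus control and the iron and immediate early calls of resolution versus acute (0.0597 for both) ended. The number of acute genes changed in the same direction at resolution was 8, and 14 without control replicates 3 and 4. With separate pairs of controls it was 8, 2, 5, 2, 4 and 2, in fits with fewer control arrays, and 2 to 10 when each array was left out. The cause was not tested for the estimated correlation, the intensity trend, the array weights and the counts without control replicates 3 and 4.

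With the covariate some differences changed sign. Scgb1a1 and Scgb3a2 belong to the list whose mean is the covariate, so a loss of their difference follows from the construction. For the other genes the cause was not tested. Scgb1a1 was then -0.22 in acute versus control, 0.023 in resolution versus control and 0.24 in resolution versus acute. In resolution versus acute Scgb3a2 was 0.47, Cyp2a5 1.36, Cd86 0.14, Idi1 0.048, Ncf1 -0.010, Itga4 -0.60, Klrk1 1.498 and Il6 0.32. Without control replicates 3 and 4 the cell cycle list in resolution versus control, not past the threshold with all arrays, passed with the opposite direction (-1.83 instead of 0.043, the negative log10 of p with the sign of the direction). No other sign change under the alternatives run involved a value past the threshold. Where neither the reported value nor the alternative was past it, 60 values of named genes and 65 of lists changed sign, such as Alas2 with a range of -2.13 to 6.10 in acute versus control. Of 1167 values of 49 named genes in acute versus control 1030 kept their side of the threshold, 132 fell short of it and 4 passed it anew. In resolution versus control these numbers were 2301, 57 and 9 of 2368 values of 99 genes, and in resolution versus acute 2240, 151 and 14 of 2414 values of 101 genes, where a gene that a stricter filter removes has no value. Of 594 list values in each comparison 549, 578 and 544 kept their side.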

Other observations

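The clock and glucocorticoid lists and the gene families below were chosen after the values had been seen, and all other lists before.

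Single genes of sugar metabolism and of the folding of secreted proteins were lower at resolution than in control, while their lists did not pass. Of 23 measured glycolysis and hypoxia genes 5 fell and 1 rose (5 and 1 adjusted over the list alone; list adjusted p = 0.205). Slc2a1, the main glucose importer, fell 2.43-fold to 15.06 ± 0.35 (SD, n = 4), Hif1a, the hypoxia-inducible factor, 2.12-fold and the glycolytic enzyme Pgam1 2.05-fold. Of 22 genes of the unfolded protein response 5 fell and 2 rose (list adjusted p = 0.322), with the chaperone Hspa5 1.71-fold lower and Herpud1 1.65-fold lower. Among 19 alternative activation genes 2 rose and 3 fell (adjusted p = 0.786). The transcription factor gene Klf4 rose 4.09-fold, while Mmp12, macrophage elastase, and Gpnmb fell 3.63-fold and 2.14-fold and the growth factor gene Igf1 fell by 1.32 ± 0.32 (SE). Control replicate 4 raised the control means of Mmp12 and Igf1, at 16.95 and 14.59 against 15.43 and 13.03 in the other controls. Of 16 chemokines 3 rose and 4 fell (adjusted p = 0.961), with Cxcl16 and Ccl22 3.19-fold and 2.71-fold lower and Ccl2 higher. Inhibitory receptors and regulators had 5 of 23 higher and 4 lower (adjusted p = 0.961), with Socs2, an inhibitor of cytokine signalling, 3.18-fold higher.

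Apart from lung epithelium, no marker list of other cells passed the threshold between resolution and control. Of 14 monocyte markers 3 rose and 2 fell (adjusted p = 0.915), with the integrin Itga4 2.05-fold higher and the receptors Treml4 and Clec4e 3.30-fold and 2.58-fold lower. Of 12 neutrophil markers 2 rose and 3 fell (adjusted p = 0.461), with Cxcr2 2.12-fold lower and Csf3r, the receptor of a granulocyte growth factor, 1.61-fold higher. Batf3 rose at least 2.99-fold among 9 dendritic cell markers (1 rose and 1 fell, adjusted p = 0.872), Ear6 fell 2.45-fold among 5 eosinophil markers (1 fell, adjusted p = 0.386) and Calcrl rose 1.68-fold among 5 endothelial markers (1 rose and 1 fell, adjusted p = 0.904). Ear6 stood at 13.71 in control replicate 4 against 12.29 in the other controls, which raised its control mean. No member of the B and plasma cell, fibroblast and red cell lists passed limma's test (adjusted p = 0.452, 0.389 and 0.828 for the lists). For the cell cycle, complement, monocyte and toll-like receptor lists here, none of them past the threshold, the median of members and the direction of the list test differed in sign. The same was so in acute versus control for inhibitory receptors, neutrophils and eosinophils, and in resolution versus acute for alternative activation, toll-like receptors, neutrophils and endothelium.

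Of 25 gene families looked through in resolution versus control 3 passed the threshold and 0 with an estimated correlation. Of 10 Kruppel-like factors 6 rose and 1 fell, also under both other scalings (adjusted p = 0.00194, and adjusted p = 0.272 with an estimated correlation), with Klf13 at 2.37 and Klf6 at -1.26. Of 3 Nr4a receptors 2 rose under each scaling (adjusted p = 0.00834, and adjusted p = 0.322 with an estimated correlation), with Nr4a2 at 2.51 beside Nr4a1. Of 22 subunits of the vacuolar proton pump 8 fell and 1 rose, Atp6v1g2 at 0.60, whose call was lost after a median shift (9 fell, 0 rose) and quantile normalization (8 and 0) (adjusted p = 0.000202, and adjusted p = 0.183 with an estimated correlation). Of 9 glucocorticoid targets 3 rose, Tsc22d3 by 2.16, Klf9 by 1.38 and Per1 by 1.12 (adjusted p = 0.0179, and adjusted p = 0.166 with an estimated correlation), and of 14 clock genes 2 rose and 2 fell (adjusted p = 0.464).

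The level of Alas2 in acute replicate 1 was 15.15 on the log2 scale, while the other acute arrays stood at 6.99 and 9.26. The red cell genes Slc4a1 and Bpgm stood at 9.55 and 8.78 in the same array, and no explanation was tested.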
